A study of Mus musculus with 28 samples.

How the data were processed

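Messenger RNA was measured by sequencing in primary macrophages grown from mouse bone marrow. Per the labels' protocols, RNA was purified with TRIzol and libraries were made with the TruSeq Stranded mRNA kit. Reads were trimmed with Trim Galore 0.6.7, aligned with HISAT2 2.2.1 to mouse build GRCm38 (also named mm10) and counted with featureCounts 2.0.1, per the submitters' processing notes. The deposited counts are raw numbers of fragments over exons, summed over genes of the same name, from featureCounts with the Ensembl annotation release 101 and no strand option, per the file headers of the M0 and 4T1 tables. The Panc02 table has no header with its command. The M0 counts deposited in 2 tables were identical for all 55367 genes and were used once. Because strand was not used in counting, values of antisense, overlapping and near-identical genes are uncertain. The second experiment was deposited by the authors as TPM, and how TPM was made is not given in the sources used here.

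Each TPM value was checked against gene lengths. Of 28043 genes above 0, values of 26823 were whole read numbers within a tolerance of 0.02 with the annotated length and of 788 with a length solved from the values, 98.5% together, and 432 were not recovered. Among the 16734 genes tested, 99.8% were recovered. These recovered reads gave the depths and 1 alternative. Coordinates are 1-based on GRCm38, from the GENCODE M21 annotation.

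Groups followed the labels, with 2 libraries in each of 3 groups with counts and 9 groups with TPM. The columns named triple were taken as the lactate, PGE2 and GM-CSF group, the only group with 3 factors and the only one not named by another column; the labels do not say so. The 2 experiments were not merged. Counts of the 6 libraries were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 by its quasi-likelihood test. TPM values of the 18 libraries were filtered to genes with a TPM of at least 1 in at least 2 libraries, transformed as log2(TPM + 1), with a pseudocount of 1, and tested with limma 3.58.1 (limma-trend). Both ran in R 4.3.3, each fitting all groups of its table in 1 model without a replicate term. Adjusted p is the Benjamini-Hochberg value within a comparison, and a gene was called under 0.05. The 18 comparisons were 3 in the count data, each of 8 groups against PBS/DMSO, 3 interactions of factor pairs, each factor added to the other 2, and the triple treatment against 4T1 conditioned medium. The log2 fold change of genes at 0 in one group depends on the prior count or pseudocount.

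Gene lists, 24 in all, were written before the data were examined, as were the groups, comparisons, thresholds and other settings. They were 14 programmes (hypoxia and glycolysis, alternative activation, inflammatory cytokines and chemokines, interferon-stimulated genes, MHC class II presentation, cAMP-responsive genes, GM-CSF and STAT5 targets, cholesterol synthesis, cell cycle, NRF2 response, lipid-associated and lysosomal genes, resident-type macrophage genes, matrix remodelling and angiogenic factors, ATF4 and unfolded protein response), 9 sets of markers (neutrophil, dendritic cell, lymphocyte, mast cell and basophil, epithelial tumour, fibroblast and stromal, erythroid, megakaryocyte, osteoclast) and mitochondrially encoded genes. Lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Camera sets a list against all other genes.

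Genes were named by a fixed rule. It took the 6 largest rises and 6 largest falls among called genes with both libraries of one group above both of the other and a mean of at least 10 CPM or TPM in the higher group. Predicted genes, unnamed identifiers, pseudogenes, ribosomal protein genes and mitochondrial genes were left out. It added up to 4 called members with the smallest adjusted p from each list with a camera call or at least 3 called members, and 10 genes always reported (Arg1, Vegfa, Mrc1, Il1b, Nos2, Chil3, H2-Ab1, Spp1, Cxcl9 and Ccl2). Interactions and added factors used 4 rises, 4 falls and 2 genes per list. Cxcl9 passed the filter of neither table. Col1a1, Sparc, Mki67 and Top2a levels at day 6 and all marker levels in the closing section were chosen after their values were seen.

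The methods were tested on simulated data. For 4T1 medium against M0, edgeR on 13146 genes recovered 38%, 74%, 94% and 100% of 50 genes each changed 1.5, 2, 4 and 8-fold, with 10 unchanged genes called. For lactate against PBS/DMSO, limma on 13502 genes recovered 22%, 72%, 90% and 98%, with 9 unchanged genes called and median ratios of estimate to truth of 0.879 to 0.942. With only 200 genes changed, these rates may not hold for more changes or the spread of PBS/DMSO. With the hypoxia list raised 2-fold in simulated Panc02 libraries, camera called 1 of 18 lists, the raised one.

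Other settings fixed in advance were the size factors of DESeq2 1.42.0 in edgeR, the Wald test of DESeq2, no filter, a replicate term, a fit of only the groups compared, a pseudocount of 0.1, quantile normalization, leaving out each library and an estimated correlation in camera. A test with edgeR on recovered reads and shares with split PBS/DMSO libraries were chosen after seeing the data. From 4 libraries of cells with a control guide or a guide against Adar, no values were available, and they were not analysed here.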

Results

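Messenger RNA of mouse bone-marrow-derived macrophages was sequenced in 2 experiments, which were kept apart here. The first held 6 libraries with deposited read counts. M0 macrophages were differentiated with M-CSF for 10 days, and 2 other groups received medium conditioned by 4T1 cells, a mouse mammary carcinoma line, or by Panc02 cells, a mouse pancreatic carcinoma line, with labels that read day 6. The second experiment held 18 libraries with deposited TPM values. Its 9 groups were the carrier control (PBS and DMSO, written PBS/DMSO), 25 mM lactate, 100 nM PGE2, 2 ng/mL GM-CSF, the 3 pairs of these factors, all 3 together (the triple treatment) and 4T1 conditioned medium. Treatment lasted 4 days, except in replicate 2 of 4T1 conditioned medium, labelled 5 days. Each group had n = 2 libraries, and the labels do not say whether these came from separate cultures or animals, so p-values measure only the spread between these samples.

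The 6 count libraries held 16589795 to 20254444 counted fragments each. The reads recovered from the TPM values came to 16741157 to 21480390 per library. Mitochondrially encoded genes took 1.13% to 2.11% of counts in the first experiment and 1.18% to 1.99% of recovered reads in the second. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom from 2.57 in M0 to 71.5 in PBS/DMSO. The PBS/DMSO libraries also differed in ribosomal protein transcripts, which took 2.17% of reads in replicate 1 and 3.48% in replicate 2, and the 4T1 day 6 libraries differed with a value of 40.9. Below, ± follows a level in CPM or TPM as the SD and a log2 fold change as its SE. For TPM data the log2 fold change is that of TPM + 1, which understates the change of genes with low TPM. For gene lists, adjusted p is that of camera with a preset correlation, and estimated-correlation p is its adjusted p with the correlation estimated from the data. Counts of list members adjusted over the list alone follow where they differ. Camera called 185 of 345 list tests, and some programme lists whose call ended under an alternative are not described. A list call sets a list against all other genes and does not say that each member moved. A range beside a list is that of its adjusted p over the alternatives.

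Macrophages in 4T1 medium at day 6 held far more arginase transcript than M0 macrophages. Arg1, which splits arginine into ornithine and urea, stood at 2.62 ± 0.403 CPM in M0 and 2320 ± 231 CPM in 4T1 medium (n = 2 each), a log2 fold change of 9.79 ± 0.19 (edgeR, adjusted p = 5.14e-07). It lies on chromosome 10, 24915221 to 24927484 of GRCm38. Vegfa, the vascular growth factor on chromosome 17, 46016993 to 46032369, went from 102 ± 0.724 to 1048 ± 254 CPM (n = 2 each, log2 3.37 ± 0.18, adjusted p = 1.37e-05). The ectonucleotidase gene Nt5e, the neutrophil-attracting chemokine gene Cxcl3, the collagenase gene Mmp8, the matrix genes Thbs1 and Fn1, and Synpo rose with log2 changes of 6.49, 4.94, 4.89, 3.78, 3.65 and 5.02 (adjusted p at most 8.80e-05), and Nos2, the inducible nitric oxide synthase, rose by 2.44 ± 0.19. Antigen presentation genes fell: H2-Eb1 (−7.53), Cd74 (−7.50), H2-Aa (−7.34) and H2-Ab1 (−3.85), as did Ciita (−6.90), the transactivator of class II genes, with adjusted p at most 6.70e-05. H2-Ab1, on chromosome 17, 34257689 to 34269419, stood at 475 ± 8.31 CPM in M0 and 32.9 ± 2.41 CPM in 4T1 medium (n = 2 each). Ccl2 fell (−3.33, adjusted p = 0.00285). Chil3 stood at 0.681 and 0.778 CPM in M0 and at 0.0503 and 0 in 4T1 medium, a called fall (adjusted p = 0.0108) that ended without M0 replicate 1 (0.0542) or 2 (0.0675, 7.12e-04 to 0.0675 over the alternatives). Mrc1, Il1b and Spp1 were not called (adjusted p = 0.546, 0.113 and 0.283).

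Of the hypoxia and glycolysis genes, 23 of 31 rose and 1 fell, with Egln3 (5.51), Aldoc (3.28) and Ero1l (2.14), while Ndrg1 fell (−3.99); camera gave adjusted p = 2.49e-16, estimated-correlation p = 0.224. The matrix and angiogenic list (19 of 27 rose and 3 fell) had adjusted p = 3.08e-08, estimated-correlation p = 0.146. Of the interferon-stimulated genes, 28 of 32 fell and 0 rose, with Ifit1 at −3.98 and Isg15 at −3.25 (adjusted p = 2.26e-19, estimated-correlation p = 0.235). ATF4 and unfolded protein genes, which include enzymes of amino acid synthesis such as Asns (−4.27) and Shmt2 (−2.56), were lower: 18 of 28 fell and 2 rose (19 and 2 over the list alone; adjusted p = 1.17e-11, estimated-correlation p = 0.224). The NRF2 list had 1 rise and 13 falls among 20 (1 and 15 over the list alone), with Srxn1 at −1.42 (adjusted p = 0.00314, estimated-correlation p = 0.528). In the class II list 7 of 14 fell and 3 rose (7 and 4 over the list alone; adjusted p = 0.00108, estimated-correlation p = 0.224), and 7 of 8 dendritic cell markers fell (adjusted p = 0.00406, estimated-correlation p = 0.271). Cholesterol synthesis genes passed camera upward with 11 rises and 0 falls among 24, Mvd among them at 1.57 (adjusted p = 0.0291, estimated-correlation p = 0.744), a call that ended without 4T1 replicate 1 (adjusted p = 0.207, range 4.33e-05 to 0.207).

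Markers of other cells moved with this medium. Neutrophil markers passed camera upward with 1 rise and 2 falls among 6 (2 and 2 over the list alone, adjusted p = 0.00945, estimated-correlation p = 0.271). The called rise was Mmp8, also held by the matrix list, and the called falls were Lcn2 and S100a9. Osteoclast markers passed downward with 0 rises and 5 falls among 7 (adjusted p = 0.0167, estimated-correlation p = 0.235). Of the fibroblast and stromal markers 7 of 11 rose and 1 fell (adjusted p = 0.0822, estimated-correlation p = 0.789), a list that passed without M0 replicate 1 (0.0361), M0 replicate 2 (0.0437) or 4T1 replicate 2 (1.16e-04, range 1.16e-04 to 0.207). The collagen gene Col1a1 was at 23.9 and 2.71 CPM in the 4T1 libraries and at 0.0486 and 0.104 CPM in M0. Erythroid markers had 1 measured member, the erythropoietin receptor, which fell, and lymphocyte markers 1 rise and 2 falls among 3; these lists were too short for camera. Proliferation genes split the 4T1 libraries. Mki67 was at 24.7 CPM in replicate 1 and 224 in replicate 2, and Top2a at 16.8 and 170 (M0 means 82 and 80.7). The 4T1 counts were deposited under a name with edu, and whether both libraries are of 1 condition, as n = 2 assumes, was not tested. The cell cycle list had no call (adjusted p = 0.469, estimated-correlation p = 0.905) and went upward without replicate 1 and downward without replicate 2. In all, 3377 genes rose and 3354 fell of 13924 tested by edgeR. The labels give M0 10 days with M-CSF and the medium groups day 6, without a total culture time. A difference in culture may therefore add to that of the medium.

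**Figure D1:**
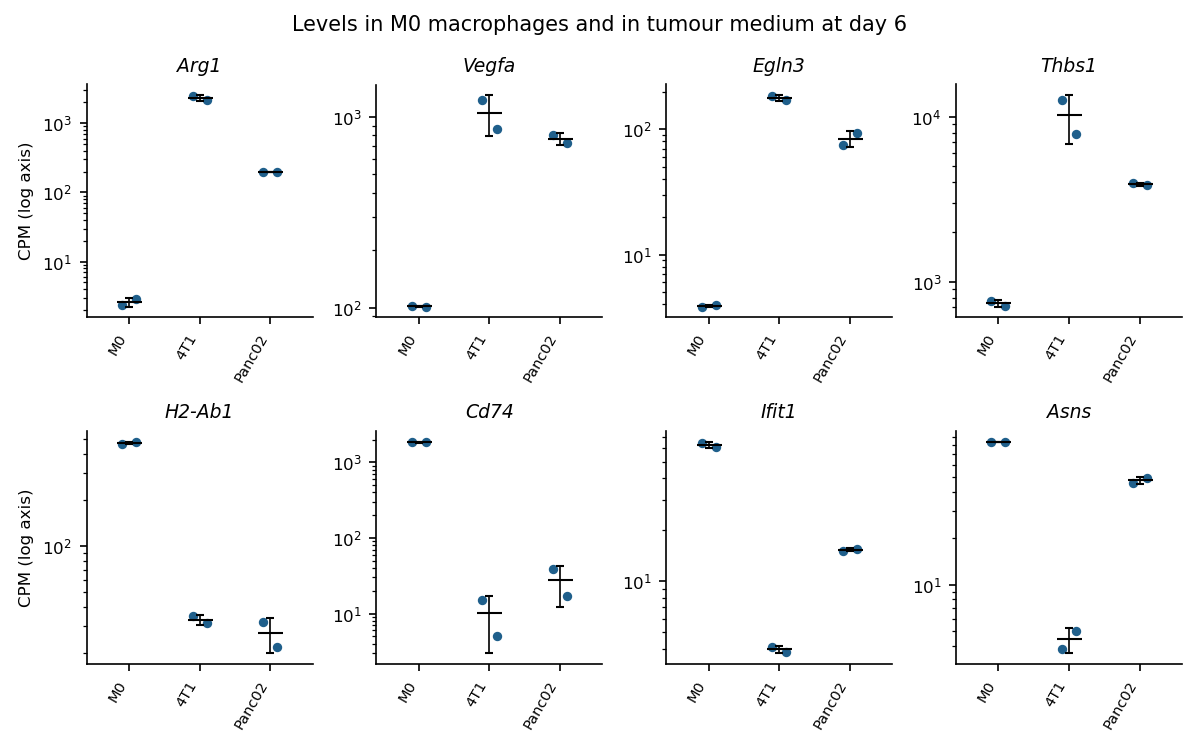
Levels of 8 genes in the 6 count libraries, in CPM on a log axis, for M0, 4T1 medium and Panc02 medium; points are libraries, and bars mark the mean ± SD of n = 2. Arg1 stands at 2.62 CPM in M0, 2320 in 4T1 medium and 198 in Panc02 medium, and H2-Ab1 at 475, 32.9 and 26.8.

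Panc02 medium raised Arg1 and Vegfa and lowered class II genes as well. Arg1 reached 198 ± 1.66 CPM (n = 2, log2 6.24 ± 0.17, adjusted p = 7.64e-06) and Vegfa 769 ± 56 CPM (n = 2, log2 2.92 ± 0.18, adjusted p = 9.26e-05). Egln3, an oxygen-sensing prolyl hydroxylase, the kinase gene Wnk2, Thbs1 and Mmp8 rose as well (4.43, 5.47, 2.40 and 1.78). H2-Ab1 was at 26.8 ± 7.01 CPM (n = 2, log2 −4.15 ± 0.18), and H2-Eb1 (−6.23), H2-Aa (−6.17), Cd74 (−6.06) and Ciita (−5.56) fell too, along with the monocyte chemokine genes Ccl8 (−5.53) and Ccl2 (−4.01), the lectin gene Cd209f (−5.38) and the serine synthesis gene Phgdh (−3.60). Adjusted p was at most 0.0027 for these.

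By list, hypoxia genes had 21 rises and 2 falls among 31 (adjusted p = 6.50e-18, estimated-correlation p = 0.271). Interferon-stimulated genes had 0 rises and 24 falls among 32 (0 and 26 over the list alone) with Ifit1 at −2.04 (adjusted p = 3.49e-10, estimated-correlation p = 0.442). Class II genes had 2 rises and 7 falls among 14 (3 and 7 over the list alone; adjusted p = 1.17e-05, estimated-correlation p = 0.234). Matrix genes had 13 rises and 5 falls among 27 (13 and 6 over the list alone; adjusted p = 6.80e-04, estimated-correlation p = 0.234). The NRF2 list, whose members detoxify oxidants, passed upward with 8 rises and 1 fall among 20, Gclm among them at 1.40 (adjusted p = 0.026, estimated-correlation p = 0.588), and lost its call without Panc02 replicate 2 (adjusted p = 0.141, range 9.10e-04 to 0.141). The complement gene C1qa (1.19) and Nos2 (1.26) rose. Cell cycle genes had 1 rise and 8 falls among 33 (0 and 5 over the list alone) with a median log2 change of −1.23 (adjusted p = 0.00387, estimated-correlation p = 0.702). Fibroblast markers had 7 rises and 0 falls among 11 (8 and 0 over the list alone; adjusted p = 0.00322, estimated-correlation p = 0.585), with Col1a1 at 11.6 and 28.9 CPM in the Panc02 libraries and Sparc at 4.22 and 11.8. Neutrophil markers passed upward with 2 rises and 0 falls among 6 (adjusted p = 0.0192, estimated-correlation p = 0.442). Dendritic cell markers passed downward with 0 rises and 5 falls among 8 (adjusted p = 0.0192, estimated-correlation p = 0.442), until Panc02 replicate 1 was left out (0.0617, range 0.00418 to 0.0617). Camera also called downward STAT5 targets (adjusted p = 0.0192, estimated-correlation p = 0.328). edgeR called 2627 rises and 2502 falls, and fewer without any single library.

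The fold changes of both media correlated across 13924 genes, which are not independent replicates (Pearson r 0.808, Spearman rho 0.776). Of the rises 2054 were shared, against 637 for independent calls, and of the falls 2010, against 603, while 66 genes were called in opposite directions. Both use the same M0 libraries. In 20 simulated draws with no other change, Pearson r averaged 0.493 (SD 0.0154) and shared calls 0.4. The covariance was 0.980 in the data and 0.0485 in the draws. The draws hold no culture difference of M0 from both media, which may also give shared changes.

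Set against each other, 4T1 medium gave more Arg1 than Panc02 medium (log2 3.55 ± 0.14, adjusted p = 1.93e-05, n = 2 each). The platelet-type chemokine genes Ppbp (6.46) and Pf4 (3.31), the neutrophil-attracting Cxcl3 (3.93), Nt5e (4.19) and Mmp8 (3.11), and the GM-CSF receptor chain Csf2rb (1.16) were also higher in 4T1 medium, and the receptor genes Fcrl5 (−6.06), Cd300e (−5.96) and Marco (−5.11) and the transporter gene Slc13a3 (−5.66) were higher in Panc02 medium (adjusted p at most 8.20e-04). In 4T1 medium 16 of 20 NRF2 genes were lower (18 adjusted over the list alone), Gclm (−1.77) and Srxn1 (−1.75) among them, as were 15 of 28 ATF4 genes (18 adjusted over the list alone), with Asns (−3.44) and Trib3 (−3.07), and 17 of 32 interferon-stimulated genes (19 adjusted over the list alone), with Ifit3 (−3.03) and Ifit1 (−1.94). Camera gave these NRF2 adjusted p = 5.53e-18, estimated-correlation p = 0.258, ATF4 adjusted p = 4.04e-18, estimated-correlation p = 0.184 and interferon adjusted p = 1.21e-14, estimated-correlation p = 0.258. The cell cycle list passed upward with 0 rises and 0 falls among 33 (adjusted p = 0.0161, estimated-correlation p = 0.752), but turned downward without 4T1 replicate 2 (2.14e-06) and was not called without Panc02 replicate 1 (0.103, range 1.84e-56 to 0.103). Megakaryocyte markers passed upward with 2 rises and 1 fall among 5 (3 and 1 over the list alone; adjusted p = 0.00894, estimated-correlation p = 0.258), as did neutrophil markers with 1 rise and 2 falls among 6 and a median of −0.20 (adjusted p = 0.0281, estimated-correlation p = 0.355), which ended without 4T1 replicate 1 (0.301) or Panc02 replicate 1 (0.176, range 3.84e-04 to 0.301). Called higher in 4T1 medium were matrix genes (adjusted p = 1.00e-07, estimated-correlation p = 0.161) and lower dendritic cell markers (0 up and 3 down of 8, 1 and 5 over the list alone, 0.00744 to 0.132, ended without 4T1 replicate 1 or 2 or Panc02 replicate 2) and osteoclast markers (0 up and 3 down of 7, 1 and 3 over the list alone, 0.013 to 0.0535, ended without Panc02 replicate 1; adjusted p 0.0276 to 0.0277, estimated-correlation p 0.258 to 0.355). H2-Ab1 (0.30) and Vegfa (0.45) were not called, with adjusted p of 0.263 and 0.107. The test gave 865 genes higher and 1171 lower in 4T1 medium. That total of 2036 rested on single libraries, coming to 3935 and 3188 without 4T1 replicate 1 or 2, and to 839 and 400 without Panc02 replicate 1 or 2; it was 857 in a fit of only these 4 libraries and 3271 with no filter.

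Lactate alone raised Arg1 from 0.526 ± 0.0556 to 196 ± 50.4 TPM (n = 2 each, log2 6.99 ± 0.30, limma adjusted p = 1.15e-07) and Vegfa from 21.5 ± 3.21 to 101 ± 3.97 TPM (n = 2 each, log2 2.18 ± 0.13, adjusted p = 1.09e-06). The coagulation factor gene F13a1 went from 3.19 ± 0.652 to 258 ± 2.23 TPM (n = 2 each), and Ch25h, an oxysterol-making enzyme, Trem1, an activating receptor, and the fractalkine receptor gene Cx3cr1 rose by 3.45, 3.37 and 2.77. Cd74, the class II invariant chain, fell (−2.66), as did the lysosomal and osteoclast genes Atp6v0d2 (−2.94) and Ctsk (−2.29), the lipase gene Lpl (−1.79), Lgals3 (−1.68), Cpe (−2.77) and Mamdc2 (−2.62) (adjusted p at most 1.29e-04).

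Hypoxia and glycolysis genes had 22 rises and 1 fall among 31 (26 and 1 over the list alone) with lactate (adjusted p = 9.09e-14, estimated-correlation p = 0.155). Lipid-associated and lysosomal genes had 4 rises and 12 falls among 24 (4 and 14 over the list alone; adjusted p = 6.70e-06, estimated-correlation p = 0.155). Osteoclast markers had 1 rise and 4 falls among 8 (1 and 5 over the list alone; adjusted p = 7.15e-04, estimated-correlation p = 0.155). Cholesterol synthesis genes had 1 rise and 6 falls among 24 (1 and 7 over the list alone; adjusted p = 0.00128, estimated-correlation p = 0.365). Resident-type genes had 7 rises and 1 fall among 20 (9 and 3 over the list alone; adjusted p = 0.00216, estimated-correlation p = 0.365). Mitochondrially encoded genes passed upward with 2 rises and 0 falls among 13 (adjusted p = 0.00702, estimated-correlation p = 0.365), which ended without PBS/DMSO replicate 1 (adjusted p = 0.485, range 2.15e-05 to 0.485). Camera also called downward ATF4 genes (adjusted p = 0.00458, estimated-correlation p = 0.365). Of 16734 genes, 1066 rose and 1262 fell, 45.8% rises against 68.7% and 32.5% without PBS/DMSO replicate 1 or 2; the calls came to 5453 without PBS/DMSO replicate 1 and to 1068 and 1231 without lactate replicate 1 or 2. A fit of only these 4 libraries called 32 genes, with 2133 at an unadjusted p under 0.05; there Egln3 (2.87), Mrc1 (−2.15), Spp1 (1.20) and Chil3 (1.85), called in the fit of all 18 libraries, had adjusted p of 0.0507 to 0.108.

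Class II genes rose with GM-CSF. H2-Ab1 went from 7.48 ± 0.608 to 580 ± 27 TPM (n = 2 each, log2 6.10 ± 0.18, adjusted p = 7.65e-10), and H2-Eb1 (6.95), H2-Aa (6.49) and Cd74 (4.92) rose with it. Itgax, the CD11c integrin, Mmp12, the macrophage elastase, Chil3, a chitinase-like lectin, Clec7a, the beta-glucan receptor, the mannose receptor Mrc1, the GM-CSF receptor chain Csf2rb, the cholesterol exporter Abcg1, the osteoclast genes Dcstamp, Atp6v0d2 and Ctsk, Hp and Mamdc2 rose by 3.44, 2.90, 2.83, 3.06, 1.44, 1.96, 3.75, 3.82, 4.01, 2.28, 5.59 and 5.02. The inhibitors of differentiation Id1 (−6.42) and Id3 (−4.77), Nptx1 (−5.51), the fractalkine receptor Cx3cr1 (−3.67), Asns (−3.23) and Tnf (−1.66) fell, with adjusted p at most 3.55e-05 for all of these. Arg1 stayed at 0.514 ± 0.516 TPM (n = 2, log2 −0.05, adjusted p = 0.93).

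With GM-CSF the class II list had 10 rises and 1 fall among 14 (adjusted p = 1.76e-10, estimated-correlation p = 0.00606). Alternative activation had 14 rises and 1 fall among 19 (14 and 2 over the list alone; adjusted p = 1.87e-09, estimated-correlation p = 0.0044). GM-CSF and STAT5 targets had 15 rises and 3 falls among 21 (16 and 3 over the list alone; adjusted p = 9.39e-09, estimated-correlation p = 0.0044). Osteoclast markers had 7 rises and 0 falls among 8 (adjusted p = 1.15e-08, estimated-correlation p = 0.0119). Lipid-associated genes had 16 rises and 3 falls among 24 (17 and 3 over the list alone; adjusted p = 3.92e-07, estimated-correlation p = 0.0495). All 33 cell cycle genes fell, all also over the list alone, with a median of −2.56; Aurka was at −2.63 and Mcm7 at −2.38 (adjusted p = 2.28e-19, estimated-correlation p = 0.105). Hypoxia and glycolysis genes had 4 rises and 21 falls among 31, with the glycolytic enzymes Eno1 (−1.39) and Pkm (−1.16) (adjusted p = 1.00e-04, estimated-correlation p = 0.312). The NRF2 list had 1 rise and 14 falls among 20 (1 and 15 over the list alone), with Gclm at −1.99 (adjusted p = 1.56e-04, estimated-correlation p = 0.0503). The ATF4 list had 2 rises and 18 falls among 27 (adjusted p = 2.56e-04, estimated-correlation p = 0.119). Dendritic cell markers had 3 rises and 0 falls among 6 (adjusted p = 0.00142, estimated-correlation p = 0.0634). Also called upward with GM-CSF were matrix genes and neutrophil markers (2 up and 0 down of 13, 9.29e-04 to 0.224, ended without PBS/DMSO replicate 1; adjusted p = 0.0124, estimated-correlation p 0.0592 to 0.532). Under limma 1899 genes rose and 4442 fell, so 29.9% of calls were rises. This split depended on a library, at 45.2% without PBS/DMSO replicate 1, and on scaling, at 47.5% with quantile normalization and 46.7% with edgeR on recovered reads, and the median of all genes was −0.106 on the log2 scale; the 4 libraries alone gave 2826 calls.

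PGE2 alone gave fewer calls than any other treatment set against PBS/DMSO. The podoplanin gene Pdpn, Thbs1, F13a1, Pf4, the lectin gene Clec4n and the chemokine gene Cxcl2 rose by 2.43, 2.34, 2.24, 2.16, 2.03 and 1.83; Pf4 went from 427 ± 130 to 1873 ± 54.4 TPM and Vegfa from 21.5 ± 3.21 to 53.3 ± 3.04 (n = 2 each, log2 1.28 ± 0.13, adjusted p = 3.81e-04). Arg1 went to 4.31 ± 1.32 TPM (n = 2, log2 1.78 ± 0.30, adjusted p = 0.00736), a call that ended without PGE2 replicate 1 (adjusted p = 0.0734, 0.00609 to 0.326 over the alternatives). Il1rn, the antagonist of the interleukin-1 receptor, the cytokine gene Osm and Spp1 rose by 1.48, 1.31 and 1.11. The scavenger protein gene Cd5l (−3.34), the interferon-induced Ifi27l2a (−1.74) and Oasl1 (−1.33), Lpl (−1.39) and Cd74 (−1.24) fell (adjusted p at most 0.00295). Inflammatory genes had 8 rises and 0 falls among 22 (9 and 0 over the list alone; adjusted p = 1.11e-08, estimated-correlation p = 0.0122). Interferon-stimulated genes had 0 rises and 18 falls among 32 (0 and 26 over the list alone; adjusted p = 1.52e-19, estimated-correlation p = 0.1). Genes that respond to cAMP had 7 rises and 1 fall among 19 (9 and 2 over the list alone; adjusted p = 1.39e-04, estimated-correlation p = 0.16). Matrix genes had 7 rises and 0 falls among 28 (14 and 3 over the list alone; adjusted p = 9.29e-08, estimated-correlation p = 0.16). Hypoxia genes had 8 rises and 1 fall among 31 (11 and 1 over the list alone; adjusted p = 2.58e-08, estimated-correlation p = 0.16). Class II genes had 2 rises and 6 falls among 14 (adjusted p = 0.00836, estimated-correlation p = 0.16), a call that ended without PBS/DMSO replicate 2 (adjusted p = 0.219, range 0.00333 to 0.219). The mast cell and basophil list had 1 measured member, the protease gene Mcpt8, which rose. Camera also called upward mitochondrially encoded genes (1 up and 0 down of 13, 5 and 0 over the list alone, 2.62e-08 to 0.407, ended without PBS/DMSO replicate 1; adjusted p = 7.41e-04, estimated-correlation p = 0.16). The fit of all 18 libraries called 292 rises and 488 falls (37.4% rises, against 52.1% with quantile normalization and 71.8% and 30.6% without PBS/DMSO replicate 1 or 2). Limma on only the 4 libraries compared called 0 genes, with 1201 at an unadjusted p under 0.05, and edgeR on recovered reads of all libraries 979; every gene named here lost its call in that small fit (adjusted p 0.117 to 0.326). Calls came to 4294 and 470 without PBS/DMSO replicate 1 or 2 and to 200 and 180 without PGE2 replicate 1 or 2.

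Lactate and PGE2 together raised Arg1 to 3807 ± 487 TPM (n = 2, log2 11.28 ± 0.30, adjusted p = 3.22e-10) and Vegfa to 277 ± 44.1 TPM (n = 2, log2 3.62 ± 0.13). Chil3 went from 0.655 ± 0.147 to 424 ± 132 TPM (n = 2 each). F13a1 (7.77), Ppbp (6.87), Fn1 (6.74), Mmp9 (6.48), Thbs1 (5.70), Egln3 (4.98), Trem1 (4.84), Cxcl2 (4.78), Pf4 (4.78) and Bnip3 (2.40) rose, where Mmp9 is a gelatinase and Bnip3 a mitophagy receptor. Proliferation genes Ube2c (−5.86), Ccnb2 (−5.82) and Aurka (−3.62), the lipid genes Lpl (−6.74) and Pparg (−3.60), Cd74 (−5.54), Itgax (−4.51) and Cd5l (−5.98), the chemokine gene Ccl2 (−2.77), Mrc1 (−1.86) and Phgdh (−4.19) fell (adjusted p at most 9.20e-05). H2-Ab1 was at 6.44 ± 1.14 TPM (n = 2, log2 −0.20, adjusted p = 0.435).

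All 33 cell cycle genes fell under the pair, all also over the list alone, with a median of −4.08 (adjusted p = 6.52e-31, estimated-correlation p = 0.174). Hypoxia genes had 26 rises and 1 fall among 31 (28 and 1 over the list alone; adjusted p = 6.87e-18, estimated-correlation p = 0.174). Matrix genes had 19 rises and 7 falls among 28 (20 and 7 over the list alone; adjusted p = 1.28e-06, estimated-correlation p = 0.293). Interferon-stimulated genes had 0 rises and 19 falls among 32 (0 and 20 over the list alone; adjusted p = 1.55e-06, estimated-correlation p = 0.293). ATF4 genes had 2 rises and 17 falls among 27 (2 and 18 over the list alone; adjusted p = 4.03e-04, estimated-correlation p = 0.293). Lipid-associated genes had 3 rises and 14 falls among 24 (3 and 15 over the list alone; adjusted p = 0.00147, estimated-correlation p = 0.293). Camera also called upward cAMP-responsive genes, cholesterol synthesis and mitochondrially encoded genes (5 up and 0 down of 13, 6 and 0 over the list alone, 2.83e-05 to 0.158, ended without PBS/DMSO replicate 1; adjusted p 0.00262 to 0.0203, estimated-correlation p 0.293 to 0.402). Also called downward were osteoclast markers (1 up and 5 down of 8, 0.00976 to 0.0773, ended without PBS/DMSO replicate 1 or 2; adjusted p = 0.0381, estimated-correlation p = 0.293). The counts were 1954 rises and 3605 falls, with rises at 35.2% of calls, 51.9% with quantile normalization and 46.6% with edgeR on recovered reads. Fitted alone, the 4 libraries gave 1823 calls.

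In lactate with GM-CSF, Arg1 stood at 888 ± 388 TPM (n = 2, log2 9.11 ± 0.30, adjusted p = 2.48e-09) and H2-Ab1 at 29.4 ± 8.38 TPM (n = 2, log2 1.81 ± 0.18). F13a1 (7.07), Chil3 (6.53), Ccl6 (5.31), Slfn1 (5.26), Ccr2 (5.07), Pf4 (4.08), Mmp8 (3.51), Vegfa (2.47), Mrc1 (1.77) and Apoe (1.75) rose, where Ccr2 is the receptor by which monocytes follow Ccl2. The urokinase gene Plau (−3.90), Tnf (−3.33), Cpe (−4.35), Lpl (−2.64) and Asns (−2.88) fell (adjusted p at most 1.11e-05). Interferon-stimulated genes had 27 rises and 1 fall among 32 (28 and 1 over the list alone), with the antiviral Mx1 (2.8) and Irf7 (1.94) (adjusted p = 1.04e-13, estimated-correlation p = 0.114). Alternative activation had 14 rises and 1 fall among 19 (15 and 1 over the list alone; adjusted p = 1.44e-07, estimated-correlation p = 0.00622). Class II genes had 8 rises and 1 fall among 14 (9 and 1 over the list alone; adjusted p = 4.35e-05, estimated-correlation p = 0.0787). Resident-type genes had 11 rises and 1 fall among 20 (12 and 2 over the list alone; adjusted p = 7.70e-05, estimated-correlation p = 0.154). NRF2 genes had 0 rises and 17 falls among 20 (0 and 18 over the list alone) and Srxn1 at −1.45 (adjusted p = 5.83e-11, estimated-correlation p = 0.00622). Cholesterol synthesis genes had 1 rise and 17 falls among 24 (1 and 18 over the list alone) and Cyp51 at −1.58 (adjusted p = 8.35e-07, estimated-correlation p = 0.135). ATF4 genes had 3 rises and 18 falls among 27 (4 and 19 over the list alone; adjusted p = 1.27e-05, estimated-correlation p = 0.114). Cell cycle genes had 0 rises and 15 falls among 33 (adjusted p = 4.23e-04, estimated-correlation p = 0.668). In total 2313 genes rose and 3109 fell; 788 were called in a fit of the 4 libraries alone, and 3577 without replicate 1 of the pair.

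PGE2 with GM-CSF left H2-Ab1 at 82.5 ± 10.7 TPM (n = 2, log2 3.29 ± 0.18, adjusted p = 1.52e-07) and Arg1 at 17 ± 1.9 TPM (n = 2, log2 3.56 ± 0.30, adjusted p = 4.04e-06). Clec4n (6.14), Thbs1 (5.34), Arg2 (5.06), Ms4a4a (5.04), Ccl6 (4.72), Vcan (4.44), H2-Aa (3.67), Vegfa (2.76), Chil3 (2.70), Csf2rb (2.22), Cxcl2 (2.12) and Mrc1 (1.78) rose, where Arg2 is the mitochondrial arginase and Vcan the proteoglycan versican. Cx3cr1 (−4.51), Cd5l (−4.45), Phgdh (−3.75), Mthfd2 (−2.93), Mcm6 (−2.53) and Hmox1 (−1.34) fell; Mcm6 is a helicase subunit of DNA replication and Hmox1 the heme oxygenase (adjusted p at most 1.02e-05). Class II genes had 9 rises and 1 fall among 14 (9 and 2 over the list alone; adjusted p = 3.80e-06, estimated-correlation p = 0.0284). GM-CSF and STAT5 targets had 14 rises and 3 falls among 21 (15 and 3 over the list alone; adjusted p = 3.80e-06, estimated-correlation p = 0.0278). Inflammatory genes had 13 rises and 2 falls among 22 (14 and 3 over the list alone; adjusted p = 5.91e-04, estimated-correlation p = 0.0409). Genes that respond to cAMP had 12 rises and 2 falls among 19 (13 and 2 over the list alone; adjusted p = 5.41e-06, estimated-correlation p = 0.0706). Neutrophil markers also passed, with 6 rises and 0 falls among 13 (7 and 0 over the list alone; adjusted p = 8.25e-04, estimated-correlation p = 0.0284), until PBS/DMSO replicate 1 was left out (adjusted p = 0.0584, range 5.76e-05 to 0.0584). Every one of the 33 cell cycle genes fell, all also over the list alone (adjusted p = 1.87e-22, estimated-correlation p = 0.0706). NRF2 genes had 1 rise and 15 falls among 20 (2 and 15 over the list alone; adjusted p = 2.32e-05, estimated-correlation p = 0.032). Other lists called upward were alternative activation, resident-type genes, matrix genes and osteoclast markers (5 up and 0 down of 8; adjusted p 3.21e-05 to 5.11e-04, estimated-correlation p 0.0284 to 0.282). Called downward were interferon-stimulated genes and ATF4 genes (adjusted p 3.05e-05 to 7.12e-04, estimated-correlation p 0.0706 to 0.352). Limma gave 1930 rises and 3405 falls, or 36.2% rises against 50.3% with quantile normalization, and 1490 calls in the 4 libraries alone.

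The triple treatment had the highest Arg1 mean of the 9 groups, 11310 ± 1625 TPM (n = 2, log2 12.85 ± 0.30 over PBS/DMSO, adjusted p = 4.28e-11), with Vegfa at 538 ± 102 TPM (n = 2, log2 4.57 ± 0.13). Chemokine genes Ppbp (10.82), Cxcl3 (9.37) and Cxcl2 (7.06), the proteases Mmp9 (7.88) and Mmp8 (6.49), Chil3 (10.57), F13a1 (8.21), Thbs1 (7.72), Vcan (7.14) and Pf4 (6.04), the mTOR inhibitor gene Ddit4 (5.63), Egln3 (5.30) and the cytokine signal suppressor Socs3 (4.5) rose. Nptx1 (−6.82), Cd5l (−6.41), Lpl (−6.07), Phgdh (−4.90), Clec12a (−4.60), Ccnb2 (−4.28), Cd74 (−3.30), Atf3 (−2.96) and Ifit3 (−2.56) fell (adjusted p at most 1.27e-05). H2-Ab1 (10.3 ± 0.0897 TPM, log2 0.42, n = 2) had an adjusted p of 0.081. Nos2 was listed at 0 in both PBS/DMSO libraries and stood at 2.22 ± 1.07 TPM in the triple treatment (n = 2), and Il1b rose by 3.87 ± 0.36.

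Under all 3 factors hypoxia genes had 27 rises and 1 fall among 31 (adjusted p = 9.97e-17, estimated-correlation p = 0.0921). Inflammatory genes had 15 rises and 5 falls among 22 (16 and 6 over the list alone; adjusted p = 2.37e-05, estimated-correlation p = 0.0713). Genes that respond to cAMP had 12 rises and 3 falls among 19 (adjusted p = 2.67e-05, estimated-correlation p = 0.103). Cholesterol synthesis genes had 11 rises and 2 falls among 24 (12 and 2 over the list alone; adjusted p = 0.00252, estimated-correlation p = 0.306). The 33 cell cycle genes all fell, all also over the list alone (adjusted p = 2.18e-24, estimated-correlation p = 0.102). ATF4 genes had 3 rises and 20 falls among 27 (4 and 20 over the list alone; adjusted p = 8.34e-05, estimated-correlation p = 0.103). Interferon-stimulated genes had 0 rises and 18 falls among 32 (0 and 19 over the list alone; adjusted p = 4.09e-04, estimated-correlation p = 0.306). Neutrophil markers passed upward with 5 rises and 0 falls among 13 (6 and 0 over the list alone; adjusted p = 0.00628, estimated-correlation p = 0.0921), a call that ended without PBS/DMSO replicate 1 (0.113, range 9.21e-04 to 0.113). Mitochondrially encoded genes passed with 2 rises and 0 falls among 13 (adjusted p = 0.0237, estimated-correlation p = 0.306), until edgeR was run on recovered reads (0.127) or PBS/DMSO replicate 1 (0.393) or triple replicate 1 (0.133) was left out (range 9.59e-04 to 0.393). Camera also called upward alternative activation and matrix genes (adjusted p 3.10e-04 to 0.00643, estimated-correlation p 0.102 to 0.306). Also called downward were NRF2 genes and lipid-associated genes (adjusted p 0.00155 to 0.00322, estimated-correlation p 0.102 to 0.191). The limma calls were 2371 rises and 4029 falls, with rises at 37% and, with quantile normalization, 49%.

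**Figure D2:**
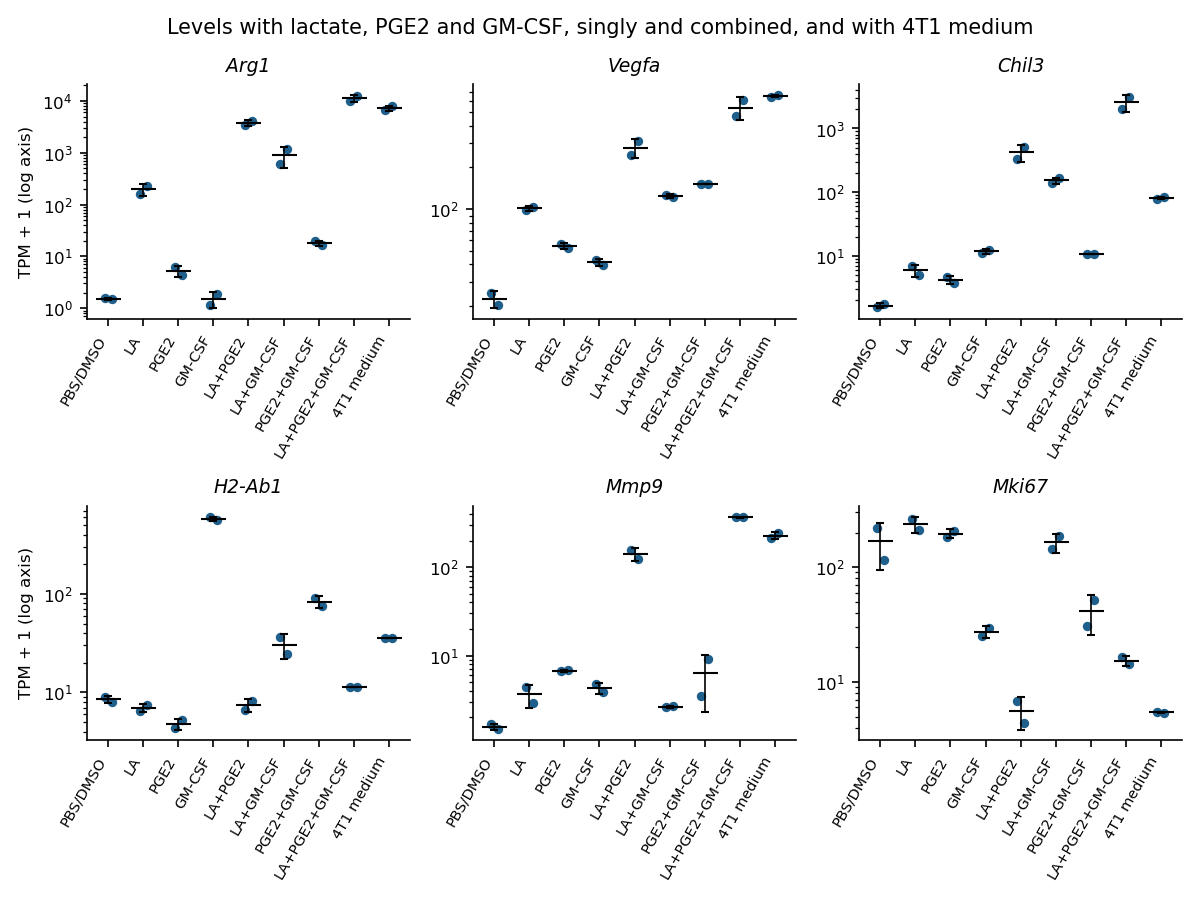
Levels of 6 genes in the 9 groups of the second experiment, as TPM + 1 on a log axis; points are libraries, and bars mark the mean ± SD of n = 2. Arg1 stands at 0.526 TPM in PBS/DMSO, 196 with lactate, 3807 with lactate and PGE2 and 11310 with all 3 factors, and H2-Ab1 at 580 TPM with GM-CSF alone.

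Interaction terms asked whether a pair of factors differed from the sum of its parts on the log2 scale, and rises and falls here are positive and negative terms. For lactate and PGE2 the proliferation genes Mki67 (−5.71), Pclaf (−5.17), Ube2c (−5.15), Top2a (−5.15) and Ccnb2 (−5.02) were lower with both than the single effects add up to. All 33 cell cycle genes were called, all also over the list alone, with a median of −4.08 (adjusted p = 9.82e-53, estimated-correlation p = 0.0837). Chil3 (4.78), Mmp8 (4.78) and Vcan (3.38), the cystine transporter Slc7a11 (2.60) and Ddit4 (1.88) were higher than the sum, and Lpl (−3.56), Ccl2 (−2.51), Il1rn (−2.21), Spp1 (−2.06) and Cd74 (−1.63) lower (adjusted p at most 0.00769). Vegfa did not pass (0.17 ± 0.19, adjusted p = 0.673), and for Arg1 (2.51 ± 0.43, adjusted p = 0.00221) the call ended with a pseudocount of 0.1 or with recovered reads, with adjusted p from 0.0019 to 0.343 over the alternatives. Cholesterol synthesis genes had 6 rises and 0 falls among 24 (adjusted p = 8.45e-06, estimated-correlation p = 0.34). There were 502 positive and 1219 negative calls (29.2% positive, 46.9% with quantile normalization). The total came to 4196 without PBS/DMSO replicate 1, 1059 without lactate replicate 1, 1111 without replicate 2 of the pair and 954 with the 8 libraries alone.

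For lactate and GM-CSF, H2-Ab1 (−4.01 ± 0.25, adjusted p = 2.18e-06) and Ciita (−3.64) were lower with both than the sum, as were the immediate early gene Egr1 (−4.13), Dcstamp (−3.23), Mmp12 (−2.15), Tnf (−1.91), Atf3 (−1.89) and Ctsk (−1.81) and the fatty acid binding protein gene Fabp4 (−1.82). Id3 (4.75), Dmpk (4.68), Adgb (4.39), Pf4 (4.17), Mrc1 (2.48), Ccnb2 (2.45) and Aurka (2.05) were higher (adjusted p at most 5.60e-04). Class II genes had 0 rises and 8 falls among 14 (0 and 10 over the list alone; adjusted p = 9.77e-14, estimated-correlation p = 0.00683). STAT5 targets had 1 rise and 9 falls among 21 (adjusted p = 1.71e-06, estimated-correlation p = 0.0131). Osteoclast markers had 0 rises and 7 falls among 8 (adjusted p = 3.55e-09, estimated-correlation p = 0.0131). Cell cycle genes had 31 rises and 0 falls among 33 (32 and 0 over the list alone; adjusted p = 2.05e-21, estimated-correlation p = 0.111). Interferon-stimulated genes had 21 rises and 0 falls among 32 (24 and 0 over the list alone; adjusted p = 1.91e-11, estimated-correlation p = 0.111). Further negative list terms were those of cAMP-responsive genes, cholesterol synthesis, lipid-associated genes, matrix genes and dendritic cell markers (0 up and 3 down of 6, 3.99e-05 to 0.193, ended with recovered reads; adjusted p 1.63e-09 to 2.48e-04, estimated-correlation p 0.0532 to 0.146). The 1466 positive and 731 negative calls (66.7% positive, 49.4% with quantile normalization) stood beside a median over all genes of 0.11. Their total was 1238 without GM-CSF replicate 2, 1349 and 1435 without lactate replicate 1 or 2, 1434 without replicate 2 of the pair, 3993 without PBS/DMSO replicate 1 and 732 in the 8 libraries alone.

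For PGE2 and GM-CSF the class II list again fell short of the sum, with 0 rises and 7 falls among 14 (0 and 8 over the list alone) and H2-Ab1 at −1.98 ± 0.25 (adjusted p = 3.57e-07, estimated-correlation p = 0.0257). Ear2 (−3.62), Pparg (−1.61), Ctsk (−1.48) and Mmp12 (−1.24) were lower and Id3 (5.30), Dmpk (5.10), Dmwd (3.82), Cd207 (4.01), Tnfsf14 (3.29), Pf4 (2.49) and Gclm (1.35) higher (adjusted p at most 0.00136). Osteoclast markers had 0 rises and 5 falls among 8 (0 and 6 over the list alone; adjusted p = 5.59e-07, estimated-correlation p = 0.0257). STAT5 targets had 1 rise and 8 falls among 21 (3 and 9 over the list alone; adjusted p = 1.41e-04, estimated-correlation p = 0.0257). Also negative were the terms of lipid-associated genes and dendritic cell markers (0 up and 3 down of 6, 1.15e-05 to 0.179, ended with recovered reads; adjusted p 1.38e-05 to 6.12e-05, estimated-correlation p 0.0307 to 0.0737). The calls were 1006 positive and 477 negative (67.8% positive, 49.3% with quantile normalization and 39.3% with recovered reads). Together they numbered 1483, and 3797 without PBS/DMSO replicate 1, 879 and 590 without GM-CSF replicate 1 or 2, 808 and 660 without PGE2 replicate 1 or 2, 641 and 917 without replicate 1 or 2 of the pair, and 257 in the 8 libraries alone.

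**Figure D3:**
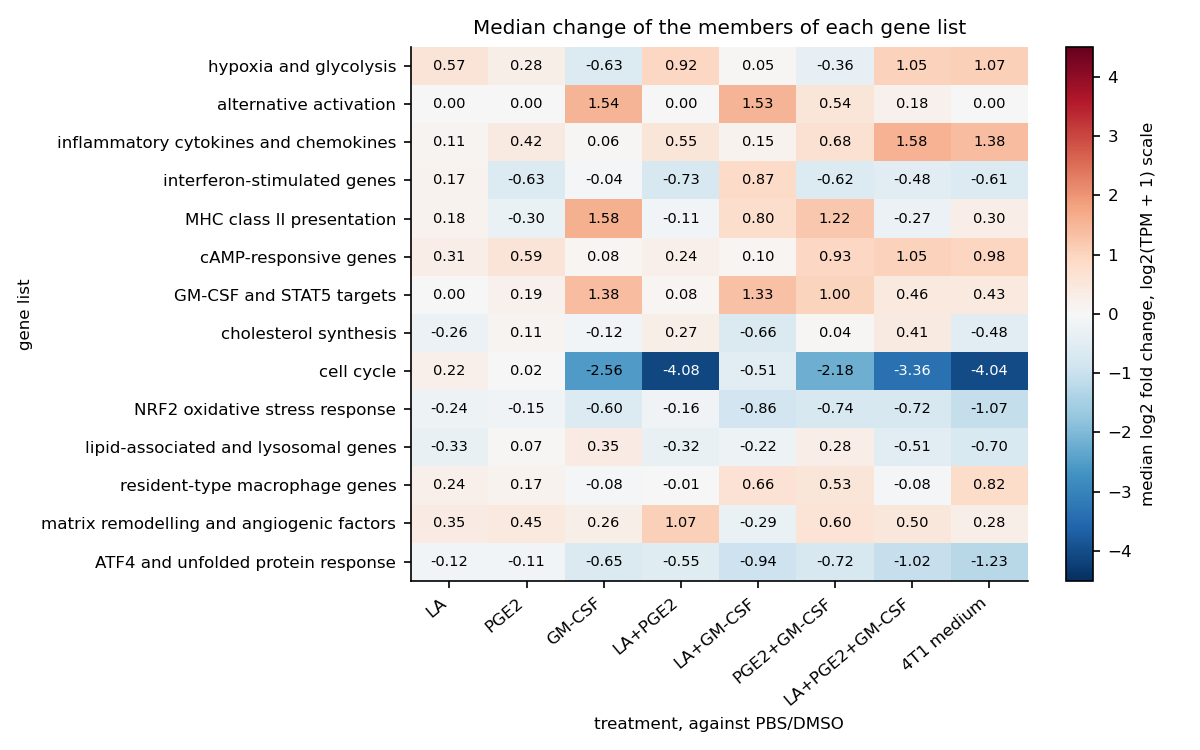
Heat map of the median log2 fold change over PBS/DMSO of 14 gene lists (vertical axis) in the 7 factor treatments and 4T1 conditioned medium (horizontal axis), from n = 2 libraries per group. The cell cycle median is −4.08 with lactate and PGE2, −3.36 with all 3 factors and −4.04 with 4T1 conditioned medium, and the class II median is 1.58 with GM-CSF.

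Each factor was also tested as an addition to the other pair. Lactate added to PGE2 and GM-CSF raised Arg1 from 17 ± 1.9 to 11310 ± 1625 TPM (n = 2 each, log2 9.29 ± 0.30, adjusted p = 1.74e-09), with Chil3 (7.87), Fn1 (7.26), Ppbp (7.18), Cxcl3 (6.94), Mmp9 (6.04), Egln3 (5.20), Cxcl2 (4.94), Bnip3 (2.49), Ccl2 (2.07) and Vegfa (1.81), and lowered Cd74 (−5.80), H2-Aa (−5.27), H2-Eb1 (−5.16), H2-Ab1 (−2.87), Atp6v0d2 (−5.19), Itgax (−4.86), Lpl (−4.49) and Mrc1 (−1.40) (adjusted p at most 0.00149). Hypoxia genes had 29 rises and 1 fall among 31 (adjusted p = 3.53e-29, estimated-correlation p = 0.0224). Inflammatory genes had 17 rises and 4 falls among 22 (17 and 5 over the list alone; adjusted p = 1.41e-05, estimated-correlation p = 0.0224). Class II genes had 1 rise and 8 falls among 14 (adjusted p = 2.61e-05, estimated-correlation p = 0.0497). Lipid-associated genes had 3 rises and 17 falls among 24 (adjusted p = 2.25e-11, estimated-correlation p = 0.0224). Camera also called upward mitochondrially encoded genes (1 up and 0 down of 13, 0.00631 to 0.26, ended with a pseudocount of 0.1 or with recovered reads or without pair replicate 2 or triple replicate 1; adjusted p = 0.0416, estimated-correlation p = 0.606). Also called downward were cell cycle and osteoclast markers (1 up and 5 down of 8; adjusted p 8.63e-12 to 3.07e-04, estimated-correlation p 0.0893 to 0.369). Lactate added 1425 rises and 1982 falls, and the calls came to 2026 without triple replicate 2.

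PGE2 added to lactate and GM-CSF raised Mmp9 (7.13), Cxcl3 (7.08), Cxcl2 (6.47), Vcan (5.68), Ddit4 (5.19), Chil3 (4.04), Arg1 (3.74), Il1b (3.02) and Vegfa (2.10) and lowered the interferon-induced Ifit2 (−4.59), Ifi206 (−4.33) and Ifit3 (−4.29), Cd5l (−4.5), Cd74 (−3.71), Ccnb2 (−3.70) and H2-Ab1 (−1.39) (adjusted p at most 9.35e-05, n = 2 each). Interferon-stimulated genes had 0 rises and 31 falls among 32 (0 and 32 over the list alone; adjusted p = 9.77e-27, estimated-correlation p = 0.0216). Hypoxia genes had 28 rises and 1 fall among 31 (29 and 1 over the list alone; adjusted p = 8.67e-26, estimated-correlation p = 0.0216). Inflammatory genes had 15 rises and 2 falls among 22 (adjusted p = 3.12e-10, estimated-correlation p = 0.00797). Cholesterol synthesis genes had 19 rises and 0 falls among 24 (21 and 0 over the list alone), with Cyp51 at 1.70 (adjusted p = 3.06e-17, estimated-correlation p = 0.0216). The whole cell cycle list of 33 genes fell, all also over the list alone (adjusted p = 5.61e-33, estimated-correlation p = 0.0526). Camera also called upward cAMP-responsive genes, NRF2 genes and matrix genes (adjusted p 1.07e-12 to 0.00149, estimated-correlation p 0.0526 to 0.0748). Also called downward were class II genes, lipid-associated genes and resident-type genes (adjusted p 1.73e-04 to 5.45e-04, estimated-correlation p 0.0526 to 0.142). There were 1343 rises and 2211 falls, 37.8% rises against 49.3% with quantile normalization, and 2329 calls without triple replicate 2.

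GM-CSF added to lactate and PGE2 raised the chemokine genes Cxcl5 (4.88), Ccl7 (4.46) and Ccl2 (4.28), Ifitm1 (4.80), the protease inhibitor gene Spint1 (4.34), Il1b (3.25), Socs3 (2.69), Chil3 (2.59), Mrc1 (2.24) and Cd74 (2.23), and lowered Cx3cr1 (−3.29), Ch25h (−2.90), Cd300e (−2.57), Gsta3 (−2.25), Hmox1 (−1.45) and Spp1 (−1.09) (adjusted p at most 9.49e-04, n = 2 each). Inflammatory genes had 12 rises and 0 falls among 22 (14 and 1 over the list alone; adjusted p = 5.83e-14, estimated-correlation p = 0.00185). STAT5 targets had 9 rises and 0 falls among 21 (11 and 3 over the list alone; adjusted p = 1.05e-07, estimated-correlation p = 0.005). Alternative activation had 7 rises and 0 falls among 19 (8 and 0 over the list alone; adjusted p = 6.67e-07, estimated-correlation p = 0.00514). Genes that respond to cAMP had 6 rises and 0 falls among 19 (7 and 0 over the list alone; adjusted p = 1.52e-08, estimated-correlation p = 0.0408). NRF2 genes had 0 rises and 9 falls among 20 (0 and 13 over the list alone; adjusted p = 3.86e-13, estimated-correlation p = 0.00328). Cell cycle genes passed upward with 10 rises and 0 falls among 33 (16 and 0 over the list alone; adjusted p = 3.79e-13, estimated-correlation p = 0.236), and neutrophil markers with 2 rises and 0 falls among 13 (adjusted p = 3.42e-04, estimated-correlation p = 0.0126). Fibroblast markers passed downward with 0 rises and 2 falls among 12 (0 and 4 over the list alone; adjusted p = 4.16e-04, estimated-correlation p = 0.455). Camera also called upward hypoxia genes and osteoclast markers (3 up and 1 down of 8, 0.00595 to 0.0547, ended without pair replicate 1 or triple replicate 1; adjusted p 0.0218 to 0.0319, estimated-correlation p 0.294 to 0.539). Also called downward were ATF4 genes (adjusted p = 2.74e-04, estimated-correlation p = 0.163). The 458 rises and 281 falls, 739 in all, came to 373 and 364 without lactate and PGE2 replicate 1 or 2, 488 and 350 without triple replicate 1 or 2, and 444 in the 4 libraries alone.

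4T1 conditioned medium in the second experiment raised Arg1 to 7315 ± 778 TPM (n = 2, log2 12.22 ± 0.30, adjusted p = 6.20e-11) and Vegfa to 651 ± 12.2 TPM (n = 2, log2 4.86 ± 0.13). The formyl peptide receptors Fpr1 (8.16) and Fpr2 (7.90), the acute phase gene Saa3 (7.36), Ppbp (8.44), F13a1 (7.88), Thbs1 (7.67), Mmp9 (7.18), Vcan (6.58), Egln3 (6.13), Cxcl2 (6.01), Socs3 (5.91), Mmp8 (5.88), Chil3 (5.62) and Il1b (7.10) and H2-Ab1 (2.08) rose, as did Mrc1 (1.03). Lpl (−7.62), Pcp4l1 (−6.68), Id1 (−6.44), Ccnd1 (−6.42), Plau (−6.41), Ccnb2 (−5.26), Spp1 (−3.99), Cx3cr1 (−3.87), Asns (−3.75), Cd36 (−2.71) and Ccl2 (−2.65) fell; Ccnd1 is a G1 cyclin and Cd36 a scavenger receptor (adjusted p at most 3.55e-04). Nos2, listed at 0 in PBS/DMSO, stood at 17.1 ± 2.45 TPM (n = 2).

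Neutrophil markers moved with this medium: 12 of 13 rose and 0 fell, with the granule genes Ngp (4.09) and Lcn2 (3.89) and the G-CSF receptor Csf3r (3.53), with adjusted p = 4.86e-08, estimated-correlation p = 0.00377. All 33 cell cycle genes fell, all also over the list alone, with a median of −4.04 (adjusted p = 2.96e-23, estimated-correlation p = 0.128). Hypoxia genes had 23 rises and 1 fall among 31 (adjusted p = 1.43e-12, estimated-correlation p = 0.128). Inflammatory genes had 14 rises and 5 falls among 22 (adjusted p = 1.58e-04, estimated-correlation p = 0.0559). Genes that respond to cAMP had 12 rises and 3 falls among 19 (adjusted p = 1.11e-04, estimated-correlation p = 0.16). Resident-type genes had 14 rises and 4 falls among 20 (adjusted p = 2.18e-04, estimated-correlation p = 0.193). NRF2 genes had 3 rises and 16 falls among 20 (4 and 16 over the list alone; adjusted p = 3.49e-05, estimated-correlation p = 0.0559). ATF4 genes had 3 rises and 19 falls among 27 (4 and 19 over the list alone; adjusted p = 5.79e-05, estimated-correlation p = 0.128). Interferon-stimulated genes had 3 rises and 20 falls among 32 (4 and 20 over the list alone; adjusted p = 0.00219, estimated-correlation p = 0.413). Of the short lists, megakaryocyte markers had 2 rises and 1 fall among 3 and epithelial tumour markers 0 rises and 1 fall among 2. Limma called 2964 rises and 4682 falls, with rises at 38.8% of calls, 49.6% with quantile normalization.

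The triple treatment was then set against 4T1 conditioned medium, where a rise is a higher level in the triple treatment. Arg1 (0.63 ± 0.30, adjusted p = 0.203) and Vegfa (−0.29 ± 0.13, adjusted p = 0.186) did not pass the test between them (n = 2 each). Id1 (7.53), Fn1 (5.51), Dmpk (5.49), Chil3 (4.95), Cd24a (4.49), Ccl2 (4.16), Trem1 (4.08), Spp1 (3.15) and Tnf (2.74) were higher in the triple treatment, and Saa3 (−8.76), Tmem176b (−6.98), Pltp (−5.65), Ass1 (−5.20), Hp (−4.36), Ngp (−4.06), Lcn2 (−3.32), Il1b (−3.23), Cd74 (−3.18), Csf3r (−2.98), Nos2 (−2.52) and H2-Ab1 (−1.66) higher in the medium; Pltp transfers phospholipids and Ass1 makes argininosuccinate (adjusted p at most 6.14e-05). Neutrophil markers were lower in the triple treatment with 0 rises and 10 falls among 13 (1 and 10 over the list alone; adjusted p = 1.18e-08, estimated-correlation p = 0.00281). NRF2 genes had 14 rises and 2 falls among 20 (15 and 2 over the list alone; adjusted p = 8.38e-07, estimated-correlation p = 0.0356). Cholesterol synthesis genes had 18 rises and 1 fall among 24 (21 and 1 over the list alone; adjusted p = 8.64e-12, estimated-correlation p = 0.0658). Cell cycle genes had 28 rises and 0 falls among 33 (32 and 0 over the list alone; adjusted p = 5.07e-14, estimated-correlation p = 0.236). Mitochondrially encoded genes had 7 rises and 0 falls among 13 (8 and 0 over the list alone; adjusted p = 1.17e-04, estimated-correlation p = 0.187). Also called lower in the triple treatment were class II genes, resident-type genes and osteoclast markers (0 up and 2 down of 8, 0.0083 to 0.0637, ended without medium replicate 2 or triple replicate 2; adjusted p 2.25e-05 to 0.029, estimated-correlation p 0.187 to 0.258). The test called 1670 genes higher and 1248 lower, 2918 together; without medium replicate 1 or 2 the calls came to 1703 and 1769, and without triple replicate 1 or 2 to 1817 and 1934.

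Across 16734 genes, the root mean square difference in log2(TPM + 1) between group means and 4T1 conditioned medium was 0.603 for the triple treatment, 0.671 for PGE2 with GM-CSF, 0.695 for lactate with PGE2, 0.797 for lactate with GM-CSF, 0.827 for GM-CSF, 1.01 for lactate, 1.02 for PGE2 and 1.05 for PBS/DMSO. Replicates of one group differed by 0.455 to 0.665 on this measure. Between single libraries the distance averaged 0.697 ± 0.00932 for the triple treatment and 0.753 ± 0.0214 for PGE2 with GM-CSF (SD over 4 pairs of libraries, which share libraries and are not independent).

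**Figure D4:**
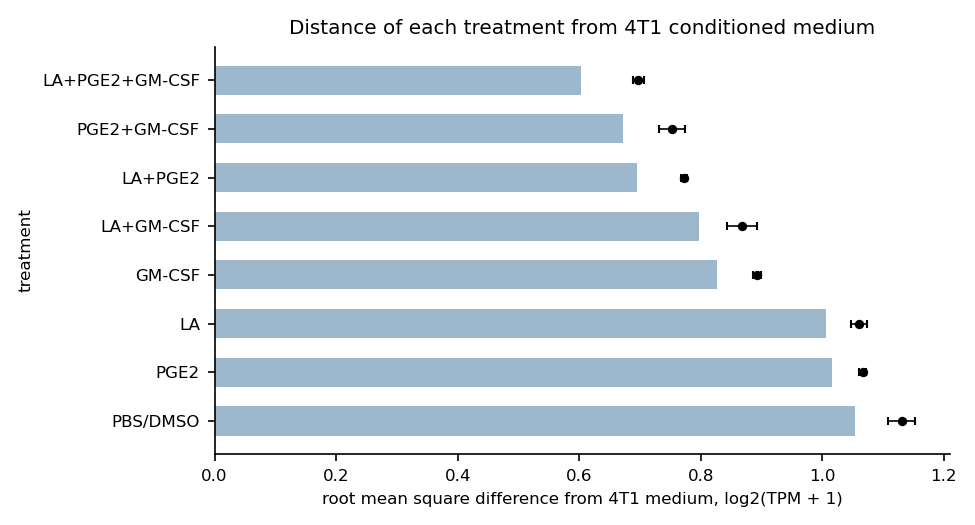
Root mean square difference in log2(TPM + 1) to 4T1 conditioned medium for the other 8 groups; bars are distances of group means from 0, and points with error bars are the mean ± SD of the 4 pairs of single libraries. The bars run from 0.603 in the triple treatment to 1.05 in PBS/DMSO.

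4T1 medium thus had a fold change in each experiment, and these were set side by side across the 13288 genes tested in both, which are not independent replicates. Pearson r was 0.320 and Spearman rho 0.399. Of the rises 1334 were shared, against 666 for independent calls, and of the falls 1856, against 1072; 787 genes were called in opposite directions. Arg1, Vegfa, Egln3, Mmp8 and Thbs1 rose in both, whereas H2-Ab1 fell at day 6 (−3.85) and rose in the second experiment (2.08). The experiments differ in control, medium time and deposited unit, and the difference between them was not tested.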

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

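Described here are interaction terms of gene lists that passed camera with at least 50% of the measured members called in 1 direction. The other results are those of the 10 fixed genes called in opposite directions in the 2 experiments. These genes needed a mean of at least 10 CPM or TPM in the higher group. That minimum leaves out Chil3, which fell at day 6 from under 1 CPM and rose with 4T1 conditioned medium. The interactions were planned, while the tests of explanations were chosen after the results were seen.

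Cell cycle genes had a median interaction of −4.08 for lactate and PGE2 (adjusted p = 9.82e-53, estimated-correlation p = 0.0837), lower in all 33 genes. The PBS/DMSO libraries, which differed from each other, were not its whole source, since the median was −4.04 and −3.87 without replicate 1 or 2. Scaling was not either, with −3.90 under quantile normalization and −4.16 with edgeR on recovered reads. PGE2 also lowered the list when added to lactate and GM-CSF, with a median of −3.05, a comparison that uses other libraries. A candidate explanation is that the 2 factors together lower the share of cycling cells, which the DNA content of the cells would test and transcript levels alone do not show.

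MHC class II genes rose with GM-CSF and had a median interaction of −1.28 with lactate and −0.74 with PGE2. B lymphocytes were not the main source, since the highest of Cd79a, Ms4a1 and Igkc in the GM-CSF libraries was 0.454 TPM, while Cd74 averaged 3711 TPM, but a small share stays open, as Ighm was at 34.8 and 40.5 TPM there, 5.15 and 7.96 in PBS/DMSO, 3.52 and 2.09 with lactate added and 7.24 and 7.64 with PGE2 added. The PBS/DMSO libraries were not the whole source of the lactate interaction, which was −1.49 and −1.23 without replicate 1 or 2. Dendritic cells in the GM-CSF cultures may contribute, since dendritic cell markers had median interactions of −1.61 with lactate and −1.35 with PGE2 (estimated-correlation p = 0.0532 and 0.0307) and of −1.06 and −1.58 with edgeR on recovered reads, where camera no longer called them for a reason not tested (adjusted p = 0.193 and 0.179, the highest of ranges from 3.99e-05 and 1.15e-05 over the alternatives). Of that list Ccl22 (25.4 TPM with GM-CSF), Batf3 (17) and Ccr7 (13.9) led the rise, Zbtb46 (1.00, 0.0939 in PBS/DMSO, 0.341 and 0.14 with lactate or PGE2 added) and Cd209a (0.748, 0, 0.108 and 0.257) went the same way at low levels, Fscn1, Xcr1 and Flt3 did not rise, Cd24a (16, 12.8, 22.5 and 4.51) rose with lactate and fell with PGE2 added, and Ccl22 is also held by 2 other lists, so this stays open beside an effect on macrophages.

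H2-Ab1 changed by −3.85 with 4T1 medium at day 6 against M0 and by 2.08 with 4T1 conditioned medium against PBS/DMSO, and the difference was not tested. H2-Aa and H2-Eb1 went the same ways. The unit was not the source, since edgeR on recovered reads gave rises of at least 1.21 for the 3 genes in the second experiment. The control groups may account for it: the mean percentile of the 3 genes among 13288 genes was 97.8 in M0 and 25.6 in PBS/DMSO, 72.2 points apart, against 33.4 and 53.1 in the 2 medium groups, 19.7 points apart. Per the labels M0 had 10 days with M-CSF and the carrier was given for 4 days, and whether such differences set the control levels was not tested.

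For lactate and GM-CSF the median interaction was 1.04 for interferon-stimulated genes, 1.93 for cell cycle genes and −1.35 for osteoclast markers (estimated-correlation p = 0.111, 0.111 and 0.0131). For PGE2 and GM-CSF it was −0.95 for osteoclast markers (0.0257).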

How the results depend on the processing

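Of the results that answer a comparison, 113 values under another setting stayed within 1.5 times or within the replicate spread of those reported and 35 moved. In fits without 1 library 67 stayed so and 73 moved. No named gene that was called reversed in any setting. Without single libraries the direction of the cell cycle list turned in both comparisons of 4T1 medium at day 6, and that of fibroblast markers with PGE2 and GM-CSF. Named genes kept their side of the threshold in 344 values with quantile normalization and gained a call in 1. With a pseudocount of 0.1 the numbers kept, gained and lost were 336, 5 and 4, and with edgeR on recovered reads, chosen after seeing the data, 334, 6 and 5. They were 82, 0 and 0 with DESeq2 size factors, 79, 1 and 2 with the DESeq2 Wald test, 421, 4 and 2 with no filter, 384, 1 and 30 in fits of only the groups compared, and 1863, 12 and 37 without single libraries. The cause of a change was not tested, but smaller fits pool less or other data, and PBS/DMSO can weigh more.

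Fitted with only the groups compared, the calls were 857 for 4T1 against Panc02 medium, 32 for lactate, 2826 for GM-CSF, 1823 for lactate with PGE2, 788 for lactate with GM-CSF, 1490 for PGE2 with GM-CSF, 2466 for the triple treatment and 4297 for 4T1 conditioned medium. PGE2 had 0 by limma. The interactions had 954 for lactate and PGE2, 732 for lactate and GM-CSF and 257 for PGE2 and GM-CSF, and GM-CSF added to lactate and PGE2 had 444. With no filter, 4T1 against Panc02 medium had 3271 calls, and the correlation of the 2 media across genes was 0.615 (Pearson r).

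With an estimated correlation camera called 40 of 345 list tests, against 185 with the preset one. Among 60 list tests 1 call was lost with DESeq2 size factors, and among 285 edgeR on recovered reads lost 11 and gained 12. Without PBS/DMSO replicate 1 or 2, 17 and 7 were lost and 3 and 14 gained. With a replicate block 343 of 345 tests stayed, and lactate had 2103 calls and PGE2 624, although replicate numbers did not pair libraries across groups (median correlation of residuals −0.00879 in TPM, 0.0651 in counts).

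The distance to 4T1 conditioned medium with a pseudocount of 0.1 was 1.27 for GM-CSF, 1.46 for lactate, 1.22 for lactate with GM-CSF, 1.10 for lactate with PGE2, 1.52 for PBS/DMSO, 1.48 for PGE2, 1.08 for PGE2 with GM-CSF and 0.995 for the triple treatment. In this order it was 0.654, 0.789, 0.630, 0.552, 0.826, 0.796, 0.534 and 0.482 with no filter. With quantile normalization it was 0.840 for GM-CSF, 0.701 for lactate with PGE2 and 1.00 for PGE2. The order of the 8 groups was the same under these 3 settings.

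Without 1 library, the sample left alone in its group is assumed to vary like the other groups. Calls then ranged from 4021 to 7873 for 4T1 medium at day 6, 2056 to 2981 for Panc02 medium and 400 to 3935 for 4T1 against Panc02 medium. They ranged from 1068 to 5453 for lactate, 180 to 4294 for PGE2 and 3577 to 6897 for lactate with GM-CSF. Without PBS/DMSO replicate 1 or 2 rises were 52% and 24.5% for lactate with PGE2, 57.9% and 30.8% for lactate with GM-CSF, 52.8% and 26.1% for PGE2 with GM-CSF and 51.1% and 26.8% for the triple treatment. For interactions calls were 1059 to 4196 for lactate and PGE2, 1238 to 3993 for lactate and GM-CSF and 590 to 3797 for PGE2 and GM-CSF. For added factors they were 2026 to 2581 for lactate, 2329 to 2770 for PGE2 and 350 to 488 for GM-CSF, and for the triple treatment against the medium 1703 to 1934. The distances ranged from 0.854 to 0.866 for GM-CSF, 1.02 to 1.04 for lactate, 0.813 to 0.857 for lactate with GM-CSF, 0.732 to 0.737 for lactate with PGE2, 1.07 to 1.12 for PBS/DMSO, 1.04 to 1.05 for PGE2, 0.699 to 0.731 for PGE2 with GM-CSF and 0.647 to 0.663 for the triple treatment.

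edgeR recovered 38% of simulated 1.5-fold changes and limma 22%, so uncalled genes may have changed.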

Other observations

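The tests of cell lineage below were chosen after the result was seen, and so were the counts of shared genes. Arg1 and Vegfa rose in both kinds of tumour medium, and many genes called with 4T1 conditioned medium were also called with the 3 defined factors. Of the 1322 genes that rose at least 2-fold with the medium, 24.1% rose with lactate (318, 84.2 for independent calls), 9.53% with PGE2 (126, 23.1) and 48.7% with GM-CSF (644, 150). With lactate and PGE2 53.9% rose (713, 154), with lactate and GM-CSF 61.5% (813, 183), with PGE2 and GM-CSF 58.2% (769, 152) and with all 3 factors 70.2% (928, 187), 273 of these with no single factor. Of the 1891 genes that fell at least 2-fold, 21.5% fell with lactate, 7.40% with PGE2, 75% with GM-CSF, 78.7%, 62.1% and 80.4% with the pairs in this order and 86.2% with all 3 factors. The shares depend on call numbers, single libraries and scaling (GM-CSF falls 4442, 3414 with quantile normalization). These comparisons share the PBS/DMSO libraries, so the medium was also set against 1 of them and the treatment against the other, in both ways. Of the rises with the medium, 44.3% and 66.9% then rose with all 3 factors, against 9.76% and 23.6% of all genes, and of the falls 82.1% and 69.9% fell, against 26.5% and 22.4%. With PGE2 alone 3.70% and 23.8% rose, against 0.868% and 18.6%.

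Of the 1322 genes, 154 had no called rise in any of the 7 factor treatments. The acute phase gene Saa3, Lcn2 and the granule gene Ngp were among the genes lower in the triple treatment.

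Of the 16 neutrophil markers, 10 were higher in both 4T1 conditioned medium libraries than in each of the other 16 libraries. Csf3r stood at 405 and 358 TPM, S100a9 at 108 and 82.4, Ngp at 30.9 and 23.6, Lcn2 at 21.2 and 19.9, Elane at 9.80 and 10.3 and Mpo at 4.20 and 3.23. S100a8, at a mean of 76.1 TPM, was nearly as high with lactate and PGE2 (58.3) and in the triple treatment (74.5), and Ly6g was at 0.261. A small share of cells of the neutrophil lineage in those cultures may account for the granule genes, and an induction of them in macrophages stays open, since no value here separates the 2. Of the list, Mmp8 is also held by the matrix list, and the macrophage gene Csf1r stood at 3226 and 3143 TPM in the same libraries.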
